A study of Mus musculus with 8 samples.

How the data were processed

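Messenger RNA was sequenced from iBMDM cells, a line of immortalized mouse macrophages derived from bone marrow, of wild-type genotype. Per the labels' protocols, cells received 5 μM disulfiram (DSF) or its solvent DMSO for 0.5 h, and then 1 μg/ml lipopolysaccharide (LPS) or water for 4 h. The 8 libraries form 4 groups of 2: control (neither agent), DSF, LPS and DSF+LPS. RNA was extracted with TRIzol and libraries were made with a VAHTS mRNA-seq kit, per the labels' protocols. The labels number the samples of a group 1 and 2 without saying whether these were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

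The authors deposited 1 table of whole-number read counts per gene, not normalized, for all 8 libraries. The genome build GRCm39 and the tool DESeq2 are named in the submitters' processing notes, without their role. The aligner, the counting tool, the annotation and the handling of strand and of reads with several matches are not given in the sources used here. Counts of near-identical genes (such as Hspa1a and Hspa1b, the Usp17 family, the clustered histone genes, Bcl2a1a, or Ifit1 and Ifit1bl1) and of overlapping or antisense genes are therefore uncertain as to which copy or strand they came from.

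The table held 55414 gene identifiers, of which 52081 matched a symbol in a reference gene list and 3333 did not; 81 of those without a symbol were tested. Symbols and the order of neighbouring genes came from the GENCODE M21 annotation of the older assembly GRCm38, so no coordinates are printed. Library totals ran from 17822041 to 21694922 counts. Levels are given as CPM, counts scaled to a common library size after the scaling named below, except sums over cell type markers, which use the plain library totals.

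Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with the quasi-likelihood test. All 8 libraries entered 1 fit with a mean for each group and no other term, so that the groups shared 1 estimate of the spread. Replicates did not vary equally in all groups, as given below. Library sizes were scaled by the trimmed mean of M-values (TMM). Genes were kept by the filterByExpr defaults (minimum count 10, minimum total count 15), which left 16304 genes. The comparisons were LPS with control, DSF with control, DSF+LPS with LPS, DSF+LPS with DSF, and the interaction, which is the LPS response with the drug minus the LPS response without it. All p-values of genes were adjusted by Benjamini-Hochberg within a comparison, and a gene is said to have risen or fallen, or to have been called, where its adjusted p was under 0.05. SE is an approximate standard error, the size of the log2 fold change divided by the square root of the F statistic of its test. Where a group had no counts of a gene, the fold is a lower bound computed with 3 counts over the group. Where a group had 1 to 3 counts, the ratio of CPM is given with a 95% counting interval. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

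The 27 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. In every comparison the rule names 10 genes (Tlr4, Ly96, Cd14, Tnf, Il1b, Il6, Nos2, Ptgs2, Cxcl10 and Ifit1), and then the 5 genes with the largest rise and the 5 with the largest fall among called genes. Those had to reach a mean of 5 CPM in the higher group, to have both samples of a group above both of the other, and not to be predicted genes. The rule adds up to 3 called members of each list. Some genes that the rule names are left out below. A gene named outside this rule was chosen after its values were seen, as were all members named because a count was 5 or smaller. The lists held 586 symbols, none of them in more than 1 list; 581 were in the table and 511 were tested.

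Lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the lists of a comparison. No p is given for the list with 1 tested member. The test was repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. For each list, members were counted by p-values adjusted over all genes tested and, separately, adjusted over the list alone. A slope through the origin relates the LPS response with the drug to that without it by total least squares, with a 95% interval from 1000 resamplings of genes. A correlation between comparisons that share the LPS libraries is set beside 100 simulations of unchanged groups.

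The scripts were tested on data simulated from these libraries with 200 genes changed in each comparison. Of genes changed 2-fold, the test recovered 77.3% for LPS with control (15662 genes), 62.1% for DSF with control (15592), 71.2% for DSF+LPS with LPS (15639), 69.2% for DSF+LPS with DSF (15609) and 50.0% for the interaction (15640). At 4-fold these shares were 81.0%, 87.1%, 90.8%, 81.0% and 75.0%, and at 1.5-fold 52.3%, 60.7%, 52.5%, 51.5% and 24.6%. False calls numbered 5, 5, 9, 15 and 5, out of 141, 137, 147, 145 and 101 calls in the same order. The false share of calls was thus above the threshold on adjusted p for DSF+LPS with LPS and for DSF+LPS with DSF. It was highest for DSF+LPS with DSF, so calls of that comparison may include more false ones than the threshold states. Simulated slopes of 0.2, 0.5 and 1 were recovered as 0.171, 0.457 and 0.955.

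Alternatives were the RLE scaling, library size alone, no filter on low counts, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a fit with the sample number as a term, a threshold of 0.5 on the log2 fold change, and leaving out each library in turn. Limma-voom with sample weights, a filter of 1 CPM in the libraries without the drug, and the alternatives of the correlation were added after the data were seen. Simulated and plotted values used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.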

Results

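Read counts per gene were obtained from 8 libraries of iBMDM cells, immortalized mouse macrophages, in 4 groups of 2. These were control (given solvent and water), disulfiram (DSF), lipopolysaccharide (LPS) and DSF followed by LPS (DSF+LPS). LPS is a bacterial cell wall component sensed by the receptor TLR4 with its partner MD-2, which the gene Ly96 encodes. DSF is a drug against alcohol dependence that inhibits aldehyde dehydrogenase. The study asked whether DSF inhibits the activation of TLR4 signalling by LPS. Totals were 17822041 and 21177025 counts in the control libraries, 21694922 and 19372143 with DSF, 21117680 and 21357810 with LPS, and 21033085 and 19637058 with both, so that depth differed little between groups.

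Libraries grouped first by the drug and then by LPS. In a principal component analysis of log2 CPM the first component held 73.9% of the variance and parted the 4 libraries with DSF from the 4 without, and the second held 14.7% and parted the libraries with LPS from those without at the same drug state. Replicate profiles correlated across genes with Pearson's r of 0.992 (control), 0.989 (DSF), 0.992 (LPS) and 0.985 (DSF+LPS), where genes are not independent replicates. The biological coefficient of variation in the common fit was 7.85%.

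Several measures of library composition differed between the groups. Genes with at least 1 count numbered 20048 ± 381 in control, 20314 ± 15 with LPS, 24479 ± 256 with DSF and 24248 ± 1177 with both (SD, n = 2). The 10 most abundant genes took 4.90% ± 0.0743 of the counts in control and 5.11% ± 0.0396 with LPS, against 7.36% ± 0.190 with DSF and 8.22% ± 0.251 with both. Ribosomal protein genes took 3.47% ± 0.152 in control, 3.42% ± 0.0826 with LPS, 4.39% ± 0.109 with DSF and 4.75% ± 0.0572 with both. Transcripts encoded by mitochondrial DNA took 1.94% ± 0.0339, 1.73% ± 0.103, 1.90% ± 0.0526 and 1.34% ± 0.0176 in control, LPS, DSF and DSF+LPS.

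LPS alone raised cytokines, chemokines and interferon-stimulated genes in these macrophages, the question being what TLR4 activation does without the drug. Tnf, which encodes tumour necrosis factor, rose 22.4-fold from 37.6 ± 0.716 to 842 ± 12.0 CPM (SD, n = 2). Cxcl10, an interferon-induced chemokine, rose from 12.0 ± 0.296 to 947 ± 87.7 CPM, and Ifit1, an antiviral interferon-stimulated gene, from 5.71 ± 0.314 to 223 ± 13.7 CPM. Ptgs2, which encodes cyclooxygenase-2, rose 93.3-fold. Of 16304 genes tested, 2485 rose and 2246 fell, 872 and 594 of them by at least 2-fold.

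Among the genes named in advance, the log2 fold changes with LPS were 4.49 for Tnf (SE 0.12, edgeR adjusted p = 6.75e-13), 6.54 for Ptgs2 (SE 0.10, adjusted p = 7.12e-15), 6.31 for Cxcl10 (SE 0.14, adjusted p = 1.47e-13) and 5.29 for Ifit1 (SE 0.10, adjusted p = 8.11e-14). Cd14, the co-receptor that passes LPS to TLR4, rose by 2.95 (SE 0.10) from 40.6 to 315 CPM. Tlr4 itself fell from 39.8 ± 2.05 to 22.4 ± 3.33 CPM (log2 fold change -0.83, SE 0.11, adjusted p = 4.70e-05). Ly96 had 2.67 ± 0.390 CPM in control and 2.90 ± 0.494 with LPS and did not pass the test (log2 fold change 0.13, SE 0.23, adjusted p = 0.744). The value was -0.03 without control replicate 2, -0.06 without LPS replicate 2 and -0.03 with library size alone. Il1b reached 592 ± 22.8 CPM, Il6 154 ± 4.50 CPM and Nos2, the inducible nitric oxide synthase, 113 ± 0.216 CPM, all from under 1 CPM. Their log2 fold changes of 9.18, 8.74 and 8.74 rested on few control counts (6 and 37, 0 and 15, and 1 and 10 in the control libraries). They were 8.51, 7.87 and 8.00 without control replicate 1, and 10.86, 14.60 and 10.93 without control replicate 2.

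The 5 largest rises by the naming rule were in secreted factors. Il12b, a subunit of interleukin-12, and Csf2 had 0 counts in control and rose at least 116-fold and at least 104-fold. Csf3, the granulocyte growth factor, rose by 9.83 on the log2 scale (9.25 without control replicate 1 and 11.10 without control replicate 2). Cxcl2, a neutrophil chemokine, rose 684-fold, and Il1b was the other. The largest falls were in Cytip (log2 fold change -3.85), Zfp395 (-3.62), Gpr157 (-3.60; -4.61 without LPS replicate 2), Lzts2 (-3.44) and Arl4c (-3.29).

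The lists of inflammatory genes moved almost as a whole. All 18 tested cytokines, all 41 interferon-stimulated genes, 16 of 17 chemokines (not Ccl6) and 26 of 27 genes of the NF-kB pathway and its feedback (not Dusp1) rose, with median log2 fold changes of 4.57, 2.57, 4.82 and 2.17. The chemokine median was 4.65 with genes of 0 control counts at their bound. Examples are Ccl7 at 29.1-fold, Rsad2 at 35.2-fold, Nfkbiz at 32.8-fold and Traf1 at 58.8-fold. Of 19 inflammatory effector enzymes and acute-phase genes 17 rose, among them Acod1, which makes itaconate, from 16.4 to 2245 CPM. The plasminogen activator gene Plau fell. Of 24 antigen presentation and costimulation genes 19 rose and none fell, with Cd40 up 11.8-fold and Tap1 3.19-fold. Adjusted over the list alone, 18, 41, 16, 27, 18 and 21 members of these 6 lists rose. All 6 lists passed camera (adjusted p from 7.18e-45 for interferon to 3.37e-13 for antigen presentation) and kept their call with an estimated correlation (adjusted p = 0.0295 for chemokines and 0.0432 for each of the others).

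Of 21 immediate early genes 12 rose and 2 fell (14 and 2 adjusted over the list alone), Maff by 4.38-fold. Klf4 and Ier5 fell. Of 29 cell cycle genes 14 fell and 2 rose (Cenpe and Cdk1), the same numbers adjusted over the list alone, with Ccnd1, the G1 cyclin D1, at 0.497 of control. Camera called both lists (adjusted p = 0.000294 and 6.96e-05), and neither with an estimated correlation (adjusted p = 0.544 and 0.256). Of 17 inflammasome and pyroptosis genes 7 rose, led by Nlrp3 at 12.7-fold, and 5 fell (9 and 5 adjusted over the list alone, and 5 and 7 with library size alone), including the ATP-gated channel P2rx7 at 0.337 of control (adjusted p of the list 0.301). The list of the TLR4 receptor complex and proximal signalling had 9 of 24 members up and 3 down (9 and 4 adjusted over the list alone; adjusted p = 0.0502; median 0.11, and -0.05 with library size alone), with the kinase genes Ikbke at 8.78-fold and Irak2 at 4.61-fold. Tlr4, Cd180 and Ticam2 fell.

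The other lists did not pass camera. Up and down were 8 and 6 of 27 NRF2 targets (10 and 7 adjusted over the list alone; 7 and 10 with library size alone), 5 and 3 of 14 metal-handling genes (6 and 5; 5 and 6 with library size alone), 4 and 0 of 19 heat shock genes (4 and 0; 2 and 4 with library size alone), 11 and 5 of 28 unfolded protein and integrated stress response genes (12 and 5), and 0 and 3 of 12 aldehyde dehydrogenases (0 and 3). All 3 falls lost the call without 1 library: Aldh9a1 without control replicate 1 or LPS replicate 2 (adjusted p up to 0.148), Aldh2 without either control library or LPS replicate 2 (up to 0.199) and Aldh6a1 without any 1 control or LPS library (up to 0.194; 0.115 with DESeq2). They were 5 and 7 of 26 glycolysis and hypoxia genes (6 and 7), 6 and 2 of 22 cholesterol biosynthesis genes (6 and 2; 4 and 5 with library size alone), 1 and 5 of 14 liver X receptor targets (1 and 5), 5 and 8 of 18 p53 targets (5 and 9) and 1 and 0 of 29 oxidative phosphorylation genes (0 and 0; 0 and 10 with library size alone). Macrophage identity genes went 8 up and 8 down of 24 (9 and 10), with a median of -0.14 and a mean of 0.06, and autophagy and lysosome genes 5 up and 8 down of 25 (6 and 11). The median and mean of metal handling (-0.01 and 0.05) and the camera and fry directions of glycolysis, p53 and macrophage identity also differed in sign. Of markers of other cell types 0 of 1 neutrophil, 1 of 6 dendritic cell, 0 of 4 lymphocyte, 1 of 2 fibroblast and 1 of 4 epithelial and endothelial genes rose and 1 dendritic cell gene fell (1, 2, 0, 1 and 1 rose and 1 fell adjusted over the lists alone). The fibroblast gene Acta2 lost the call without control replicate 2 or LPS replicate 1 (adjusted p up to 0.111) and Kdr without control replicate 2 or LPS replicate 2 (up to 0.0790). The dendritic cell list had a median of -0.33 and a mean of 1.12, and no such list summed to over 17.0 CPM in a control or LPS library.

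Without control replicate 2, 3146 genes were called in place of 4731. Scaling by library size alone shifted the median log2 fold change of all genes by -0.14 and turned the split from 52.5% to 30.0% of calls upward, while cytokines, chemokines, NF-kB, interferon, effector and antigen presentation lists still rose.

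**Figure D1:**
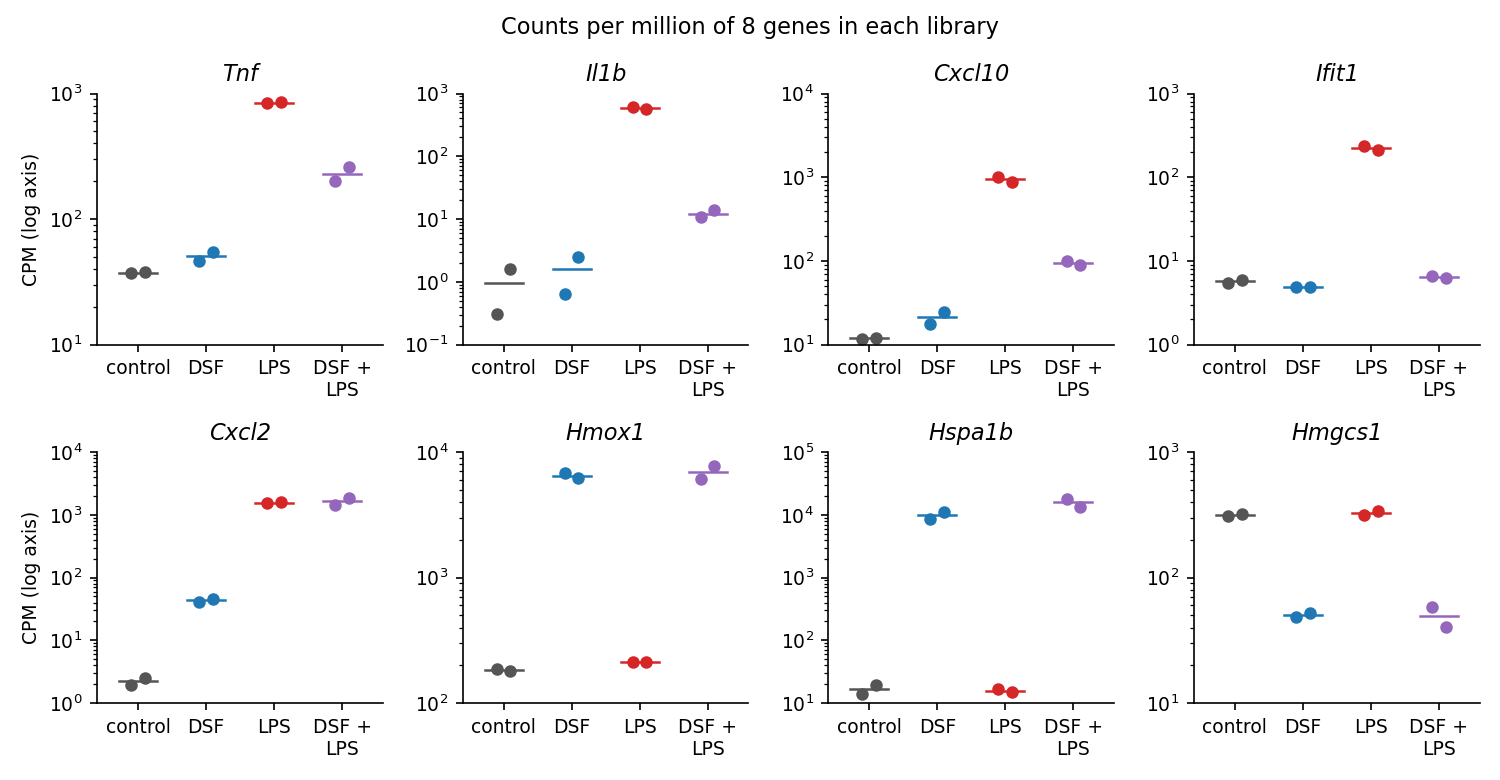
CPM of 8 genes on a log axis in the 8 libraries, by group; dots are single libraries and lines are means of 2. With LPS alone Tnf, Il1b, Cxcl10, Ifit1 and Cxcl2 stand high; with DSF before LPS the first 4 are lower (230, 12.2, 94.6 and 6.44 CPM) and Cxcl2 is not (1664 CPM), while Hmox1 and Hspa1b are high and Hmgcs1 is low in all 4 libraries with DSF.

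DSF alone, compared with control to show what the drug does without LPS, raised genes of protein damage and oxidative stress and lowered genes of cholesterol synthesis. Hspa1b, an inducible HSP70 chaperone, rose from 16.7 ± 3.70 to 9818 ± 1733 CPM (SD, n = 2), and Hmox1, the heme-degrading enzyme induced by NRF2, from 185 ± 5.04 to 6473 ± 409 CPM. Mt1, a metal-binding metallothionein, rose from 373 ± 8.79 to 3755 ± 332 CPM. Hmgcs1, an early enzyme of the cholesterol pathway, fell from 317 ± 9.90 to 50.5 ± 2.37 CPM. Of 16304 genes 5049 rose and 4418 fell, 2870 and 845 of them by at least 2-fold. With library size alone 4423 rose and 5269 fell.

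Of 19 tested heat shock genes 18 rose and 1, the regulator Hsf1, fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 1.71. Hspa1b rose by 9.19 (SE 0.19, adjusted p = 1.28e-13), Hspa1a by 9.67 (SE 0.22) and Hsph1 by 3.57 (SE 0.07). How reads were split between Hspa1a and Hspa1b is uncertain. Of 27 NRF2 targets 25 rose and none fell (25 and 0 adjusted over the list alone), the exceptions being G6pdx and Tkt. Hmox1 rose 35.1-fold (adjusted p = 7.69e-14), the cystine transporter Slc7a11 29.7-fold and the autophagy receptor Sqstm1 8.12-fold. Of 21 immediate early genes 19 rose, all by at least 2-fold (19 adjusted over the list alone), Maff 12.9-fold and Jund 7.17-fold. Klf2 and Nr4a1 did not pass, at log2 fold changes of 0.22 and 0.16. Of 28 unfolded protein and integrated stress response genes 21 rose and 4 fell (21 and 5 adjusted over the list alone). Those that rose included Trib3 (29.4-fold) and Ppp1r15a (18.8-fold), targets of the integrated stress response, whereas the endoplasmic reticulum genes Xbp1, Pdia4, Manf and Creld2 fell. Of 14 metal-handling genes 9 rose and 2 fell (9 and 3 adjusted over the list alone), with Mt2 at 12.8-fold and the zinc exporter Slc30a1 at 5.12-fold. Slc39a10 and Slc30a4 fell.

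All 22 cholesterol biosynthesis genes fell (22 adjusted over the list alone), 15 of them by at least 2-fold, with Hmgcs1 at 0.159, Lss at 0.307 and Sqle at 0.379 of control. Of 29 cell cycle genes 20 fell and none rose, the same numbers adjusted over the list alone. Ccnd1 fell to 0.407 and Rrm1, a subunit of ribonucleotide reductase, to 0.468 of control. Of 24 macrophage identity genes 15 fell and 3 rose (15 and 3 adjusted over the list alone). The transcription factor gene Maf fell to 0.125 of control and Tlr2 to 0.194, while Cd68 and Lyz2 were among those that rose. Of 25 autophagy and lysosome genes 16 rose and 4 fell (16 and 4 adjusted over the list alone), Optn 10.8-fold and Gabarapl1 4.18-fold. Tfeb and Mitf were among those that fell, and with library size alone the numbers were 10 and 5.

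Inflammatory genes went both ways with DSF alone. Of 41 interferon-stimulated genes 25 fell and 5 rose (25 and 5 adjusted over the list alone), with Parp14 at 0.250 and Oasl2 at 0.320 of control. Mx1, Mx2, Isg20, Rsad2 and Slfn4 rose. Of 18 cytokines 11 rose and 1, Il15, fell (11 and 1 adjusted over the list alone), Osm by 7.16-fold and Csf1 by 6.33-fold. The median log2 fold change was 1.90, or 0.77 with genes of 0 control counts at their bound. Ptgs2 rose by 3.15 (SE 0.09), Cd14 by 1.61 (SE 0.10) and Cxcl10 by 0.82 (SE 0.14). Ly96 rose 3.03-fold from 2.67 ± 0.390 to 8.08 ± 0.0343 CPM (log2 fold change 1.60, SE 0.21, adjusted p = 1.25e-05). Tnf rose by 0.42 (adjusted p = 0.00425), and by 0.27 without DSF replicate 2 (adjusted p = 0.0651). Tlr4 fell by 0.30 on the log2 scale (adjusted p = 0.0303). Without control replicate 1, control replicate 2 or DSF replicate 2 the values were -0.36, -0.26 and -0.28 (adjusted p = 0.0528, 0.164 and 0.114). Ifit1 did not pass (log2 fold change -0.22, adjusted p = 0.161).

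Il1b, Il6 and Nos2 were at or under 1.58 CPM with and without DSF and did not pass, with log2 fold changes of 0.59, 0.37 and 0.56 (adjusted p = 0.396, 0.685 and 0.467). Each value was set by single libraries. Without control replicate 2 they were 2.26, 6.22 and 2.75 (adjusted p = 0.0334, 0.00494 and 0.0321), and without control replicate 1 they were -0.09, -0.52 and -0.18. Il1b was 1.29 without DSF replicate 1 (adjusted p = 0.0289) and -0.70 without DSF replicate 2, and Il6 was -0.18 without DSF replicate 2.

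Among the largest rises, in genes with 0 counts in control, were the homeobox gene Uncx (at least 123-fold), the calcium channel gene Cacna1h (at least 117-fold), Mmp28 (at least 117-fold) and Usp17le (at least 110-fold; its fitted log2 fold change of 10.34 was 9.75 without DSF replicate 2). The largest falls were in Asb2 (log2 fold change -4.32), the purine receptor gene P2ry13 (-3.88), Nxpe1-ps (-3.77), Ighm (-3.75) and the oxysterol receptor gene Gpr183 (-3.37).

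Camera called 11 lists, each with a median that had the direction of its test. Adjusted p was 6.90e-11 for heat shock, 6.88e-11 for NRF2 and for immediate early genes, 4.44e-06 for the unfolded protein and integrated stress response, 0.0149 for metal handling and for autophagy, 0.0162 for cytokines, 1.34e-13 for cholesterol biosynthesis, 5.89e-08 for the cell cycle, 0.000350 for macrophage identity and 0.000148 for interferon. None held with an estimated correlation, where adjusted p = 0.277 for heat shock, metal handling, cholesterol and cell cycle, 0.308 for macrophage identity, 0.321 for NRF2, immediate early and unfolded protein genes, 0.395 for autophagy and 0.495 for interferon and cytokines. The cytokine call was also lost without control replicate 1 (adjusted p = 0.0643), and scaling by library size alone shifted the median of all genes by -0.10.

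Among lists that did not pass, up and down were 8 and 11 of 24 TLR4 complex genes (8 and 11 adjusted over the list alone; median 0.04, mean -0.006, median -0.06 with library size alone), 5 and 2 of 17 chemokines (5 and 2), 12 and 9 of 27 NF-kB genes (12 and 9), 4 and 9 of 17 inflammasome genes (4 and 9) and 7 and 5 of 19 effector genes (7 and 5; median 0.03, and -0.08 with library size alone). They were 4 and 4 of 12 aldehyde dehydrogenases (4 and 4; median -0.20, mean 0.09), 10 and 10 of 26 glycolysis genes (10 and 11), 4 and 7 of 14 liver X receptor targets (4 and 7), 7 and 9 of 18 p53 targets (7 and 9), 4 and 8 of 29 oxidative phosphorylation genes (4 and 7) and 8 and 5 of 24 antigen presentation genes (8 and 5). Camera pointed down and fry up for p53 targets and for the TLR4 complex. The adaptor gene Myd88 fell to 0.419 of control, the phosphatase gene Dusp1 rose 35.7-fold and Cxcl2 rose 19.2-fold. Among markers of other cell types, 1 of 1 neutrophil, 3 of 6 dendritic cell, 2 of 4 lymphocyte, 1 of 2 fibroblast and 2 of 4 epithelial and endothelial genes rose and none fell, the same numbers adjusted over the lists alone. Calls were lost without 1 library for the neutrophil gene Camp (adjusted p up to 0.220; 0.0665 with DESeq2), the dendritic cell genes Xcr1 (up to 0.0918) and Itgax (up to 0.0829), the endothelial gene Pecam1 (0.0602) and the fibroblast gene Acta2. The last was lost without any 1 control or DSF library (up to 0.115; 0.0529 with DESeq2). The largest sum over any of these marker lists in a DSF library was 18.1 CPM, for dendritic cell markers, which summed to 15.9 and 17.0 CPM in the control libraries.

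DSF before LPS was compared with LPS alone to ask how the drug alters the LPS-treated state. Interferon-stimulated genes, chemokines and many cytokines were far lower with DSF, and the stress genes raised by DSF alone were high here too. Ifit1 fell 34.6-fold, from 223 ± 13.7 to 6.44 ± 0.237 CPM (SD, n = 2), against 5.71 ± 0.314 CPM in control. Il1b fell 48.4-fold, Il6 44.4-fold, Nos2 51.3-fold, Cxcl10 10.0-fold and Tnf 3.66-fold, while Cxcl2 had 1555 ± 31.9 CPM with LPS and 1664 ± 309 CPM with both (log2 fold change 0.10, not called). Of 16304 genes 5497 were higher and 5156 lower, 3141 and 1609 of them by at least 2-fold. With library size alone 5184 were higher and 5465 lower.

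In log2 terms Ifit1 fell by 5.11 (SE 0.10, edgeR adjusted p = 4.60e-14), Il1b by 5.60 (SE 0.23, adjusted p = 3.87e-11), Il6 by 5.47 (SE 0.22, adjusted p = 2.99e-11) and Nos2 by 5.68 (SE 0.19, adjusted p = 4.54e-12). Cxcl10 fell by 3.32 (SE 0.11), Tnf by 1.87 (SE 0.10), Ptgs2 by 1.71 (SE 0.08) and Cd14 by 0.89 (SE 0.10, adjusted p = 1.32e-06). Ly96 was 2.58-fold higher than its 2.90 ± 0.494 CPM with LPS alone (log2 fold change 1.37, SE 0.21, adjusted p = 4.33e-05). Tlr4 had 20.8 ± 0.406 and 22.4 ± 3.33 CPM and did not pass (log2 fold change -0.11, SE 0.12, adjusted p = 0.437; 0.04 without LPS replicate 1).

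All 41 tested interferon-stimulated genes fell, each by at least 2-fold (41 adjusted over the list alone), with a median of -3.62; Ifit2 was at 0.0229 and Parp14 at 0.0316 of LPS alone. Of 17 chemokines 15 fell (15 adjusted over the list alone), Ccl7 to 0.0659 and Ccl9 to 0.101, and Cxcl2 and Cxcl3 did not pass. Of 18 cytokines 13 fell, Csf3 to 0.0432 of LPS alone, and 2 rose, Il23a and Csf1 (13 and 2 adjusted over the list alone). Of 27 NF-kB pathway genes 20 fell and 5 rose (20 and 5 adjusted over the list alone), Birc3 to 0.189 and Tnip1 to 0.259. Dusp1, Dusp2, Dusp16, Nfkbib and Relb rose. Of 19 effector genes 12 fell, such as the oxidase subunit Cybb to 0.127 of LPS alone, and 4 rose, among them Arg2, Ptges and Gch1, with 13 and 4 adjusted over the list alone. Of 17 inflammasome genes 10 fell, Nlrp3 to 0.388, and 4 rose (Mefv, Ninj1, Aim2 and P2rx7), with 10 and 4 adjusted over the list alone.

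Stress genes were again higher: 18 of 19 heat shock genes (18 adjusted over the list alone), with Hspa1b at 15700 ± 3238 CPM, and 24 of 27 NRF2 targets with 1 lower, Gsr (24 and 1 adjusted over the list alone), with Hmox1 at 32.5-fold. Of 21 immediate early genes 18 rose (18 adjusted over the list alone), Egr1 65.2-fold and Ier5 7.25-fold. Of 28 unfolded protein and integrated stress response genes 21 rose and 4 fell (21 and 4 adjusted over the list alone), Trib3 20.7-fold. Manf, Creld2, Pdia4 and Xbp1 fell. Of 25 autophagy genes 19 rose and 4 fell (19 and 4 adjusted over the list alone), Ulk1 6.20-fold. Tfe3, Lamp2, Mitf and Atg5 fell. Cholesterol genes fell in 19 of 22 cases (21 adjusted over the list alone), Hsd17b7 to 0.191 and Lss to 0.273 of LPS alone. Of 29 cell cycle genes 18 fell and 4 rose (18 and 4 adjusted over the list alone), Top2a to 0.364. Pcna, E2f1, Mcm5 and Mcm7 rose. Of 24 macrophage identity genes 14 fell and 7 rose (14 and 7 adjusted over the list alone), Tlr2 to 0.0907 and the scavenger receptor gene Msr1 to 0.149.

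The largest rises were in genes with 0 counts in LPS alone: Hfm1 (at least 318-fold), the sodium channel gene Scn4a (at least 267-fold), Fam117a (at least 195-fold), Plekha6 (at least 173-fold) and Uncx (at least 162-fold). Fitted log2 fold changes were 11.61 for Scn4a (10.69 without DSF+LPS replicate 1) and 10.89 for Uncx (9.90 and 11.49 without DSF+LPS replicates 1 and 2). The largest falls were in Clec2d (log2 fold change -6.82; -7.70 without DSF+LPS replicate 1), Gbp5, an interferon-induced GTPase (-6.51), Otor, Il12b (-5.91; -5.21 and -7.17 without DSF+LPS replicates 1 and 2) and Mmp8. Otor had 3 and 0 counts with both agents and Mmp8 1 and 2, and they were 64.7-fold (counting interval 21.8 to 316) and 64.1-fold (21.6 to 313) higher with LPS alone. The fitted value of Otor was -5.91, and -9.70 and -4.996 without DSF+LPS replicates 1 and 2.

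Camera called 14 lists. Adjusted p was 1.48e-23 for interferon, 6.67e-08 for chemokines, 3.07e-05 for cytokines, 3.48e-05 for NF-kB, 0.000544 for effector genes and for autophagy, 0.0410 for inflammasome genes, 4.19e-09 for heat shock, 7.89e-09 for NRF2, 1.82e-08 for immediate early genes, 5.31e-06 for the unfolded protein list, 5.80e-11 for cholesterol, 0.00130 for the cell cycle and 0.0432 for macrophage identity. With an estimated correlation none held, at adjusted p = 0.184 for interferon, chemokines, heat shock and cholesterol, 0.406 for macrophage identity and 0.244 for each of the other lists called.

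Lists that did not pass had, up and down, 6 and 12 of 24 TLR4 complex genes (6 and 12 adjusted over the list alone; adjusted p = 0.126), 8 and 5 of 14 metal-handling genes (9 and 5), 6 and 15 of 24 antigen presentation genes (6 and 15; adjusted p = 0.0697), 3 and 2 of 12 aldehyde dehydrogenases (3 and 2; median 0.04, and -0.007 with library size alone), 11 and 9 of 26 glycolysis genes (12 and 9; 10 and 12 with library size alone), 7 and 6 of 14 liver X receptor targets (7 and 6; median -0.02 with library size alone), 8 and 8 of 18 p53 targets (8 and 9) and 11 and 9 of 29 oxidative phosphorylation genes (11 and 9). Medians and means differed in sign for p53 targets (-0.16 and 0.12) and oxidative phosphorylation (-0.02 and 0.10, with a median of 0.009 under relative log expression scaling), and the camera direction was down for liver X receptor targets with a median of 0.03 and a mean of 0.21. Fry pointed down and camera up for glycolysis. Mt1 rose to 4739 ± 200 CPM, Myd88 fell to 0.374, Ikbke to 0.209 and Tap1 to 0.164 of LPS alone, and Cd74 rose 2.20-fold. Among the other cell types 3 of 6 dendritic cell markers and 2 of 4 lymphocyte markers rose, 2 of 4 epithelial and endothelial markers rose and 1 fell (Kdr, log2 fold change -0.71; -0.41 and adjusted p = 0.0634 without DSF+LPS replicate 2), and no neutrophil or fibroblast marker passed. Calls were also lost without 1 library for Flt3 (adjusted p up to 0.104), Itgax (up to 0.129; 0.0628 with DESeq2), Cd79a (0.105), Cldn4 (0.158) and Pecam1 (up to 0.163).

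With the drug present, LPS was compared with no LPS (DSF+LPS with DSF) to measure the response that remained. Most NF-kB genes and part of the cytokines and chemokines rose, and interferon-stimulated genes mostly did not pass. Tnf rose 4.57-fold, from 50.4 ± 5.88 to 230 ± 40.2 CPM (SD, n = 2), Cxcl10 4.47-fold and Ptgs2 3.21-fold. Cxcl2 rose 38.1-fold and reached 1664 ± 309 CPM. Of 16304 genes 901 rose and 1065 fell, and 105 and 39 of them by at least 2-fold.

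The largest rises were in Cxcl2 (log2 fold change 5.25, SE 0.12, edgeR adjusted p = 1.94e-12), Csf3 (4.65, SE 0.26), Acod1 (4.55, SE 0.17), Il1b (3.00, SE 0.36, adjusted p = 0.000110) and the fatty acid receptor gene Gpr84 (2.91, SE 0.16). Without DSF replicate 1 the value of Il1b was 2.28, and without DSF replicate 2 it was 4.27. Tnf rose by 2.19 (SE 0.11), Cxcl10 by 2.16 (SE 0.12), Il6 by 2.90 (SE 0.44, adjusted p = 0.00102), Nos2 by 2.49 (SE 0.40, adjusted p = 0.00138), Ptgs2 by 1.68 (SE 0.08) and Cd14 by 0.45 (SE 0.10, adjusted p = 0.00909). DESeq2 did not call Il6 (adjusted p = 0.0711), and a fit of only these groups did not call Cd14 (0.46, adjusted p = 0.0629). Ifit1 had 4.90 ± 0.0114 CPM without and 6.44 ± 0.237 with LPS and did not pass (log2 fold change 0.40, SE 0.13, adjusted p = 0.0641), although it did with 2 stricter filters on low counts (adjusted p = 0.0489 and 0.0423). Tlr4 fell by 0.63 on the log2 scale (adjusted p = 0.00351; -0.57 and adjusted p = 0.0502 without DSF replicate 1). Ly96 did not pass (log2 fold change -0.11, SE 0.19, adjusted p = 0.782; 0.02 without DSF+LPS replicate 2). The largest falls were in Gpr183 (log2 fold change -1.51), the mitochondrial gene mt-Nd6 (-1.50), Fam78a (-1.28), Zfp946 (-1.26) and Cbx3-ps7 (-1.25).

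Of 27 NF-kB genes 24 rose and none fell (25 adjusted over the list alone), with Nfkbiz at 5.30-fold and Traf1 at 4.94-fold. Socs1, Bcl2a1a and Tnfaip2 did not pass. Of 17 chemokines 9 rose (10 adjusted over the list alone), Ccl4 3.23-fold, and of 18 cytokines 11 rose (11 adjusted over the list alone), Lif 4.16-fold. Of 19 effector genes 9 rose (11 adjusted over the list alone), Mmp13 4.66-fold. Of 24 antigen presentation genes 5 rose (6 adjusted over the list alone), namely Cd40, Cd74, H2-K1, H2-D1 and H2-Q4. Of 41 interferon-stimulated genes 6 rose and 3 fell (7 and 6 adjusted over the list alone), with a median log2 fold change of 0.001 and a mean of -0.03. Oasl1 rose 1.60-fold and Isg15 1.72-fold (log2 fold change 0.78; 0.59 and adjusted p = 0.0515 without DSF replicate 1), and Ifi204, Trim30a and Ifi47 fell, the last by 1.40 on the log2 scale (-1.30 and adjusted p = 0.0748 without DSF replicate 1; adjusted p = 0.0718 in a fit of only these groups). With library size alone 4 of the list rose and 8 fell, with a median of -0.10.

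Of 21 immediate early genes 6 rose (8 adjusted over the list alone), Maff 1.63-fold. Of 28 unfolded protein and integrated stress response genes 8 rose (10 adjusted over the list alone), and of 29 oxidative phosphorylation genes 10 rose and 1, Cycs, fell (13 and 2 adjusted over the list alone). Of 29 cell cycle genes 10 fell (11, with 2 up, adjusted over the list alone), Ccnd1 to 0.508 and Top2a to 0.722. Under library size alone the counts rising were 3 immediate early, 3 unfolded protein and 5 oxidative phosphorylation genes. Camera called 9 lists, at adjusted p = 1.32e-34 for NF-kB, 1.02e-11 for chemokines, 3.56e-09 for cytokines, 1.52e-11 for effector genes, 9.18e-06 for antigen presentation, 2.32e-06 for immediate early genes, 3.55e-05 for the unfolded protein list, 5.53e-05 for oxidative phosphorylation and 0.00216 for the cell cycle, which was lost without DSF+LPS replicate 2 (adjusted p = 0.133). With an estimated correlation NF-kB and chemokines kept the call (adjusted p = 0.0449 for each), and the others did not, at adjusted p = 0.107 for effector genes, 0.185 for cytokines and antigen presentation, 0.426 for immediate early, unfolded protein and cell cycle genes and 0.475 for oxidative phosphorylation. The interferon list did not pass (adjusted p = 0.958).

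In the remaining lists up and down were 5 and 2 of 24 TLR4 complex genes (6 and 3 adjusted over the list alone; median -0.03, mean 0.09), with Ikbke 4.91-fold up, 4 and 3 of 17 inflammasome genes (4 and 4; median -0.10, mean 0.18; 3 and 5 with library size alone), with Nlrp3 up by 1.62 on the log2 scale, 5 and 1 of 27 NRF2 targets (6 and 1; 1 and 3 with library size alone), 4 and 5 of 14 metal-handling genes (6 and 5; median 0.08, and -0.02 with library size alone) and 5 and 3 of 19 heat shock genes (9 and 4; 3 and 5 with library size alone). They were 1 and 0 of 12 aldehyde dehydrogenases (1 and 0; 0 and 1 with library size alone; the call, Aldh2, was lost without any 1 library other than DSF+LPS replicate 2, at adjusted p up to 0.188), 3 and 2 of 26 glycolysis genes (9 and 5; median 0.14, mean -0.007; 1 and 5 with library size alone), 2 and 2 of 22 cholesterol genes (2 and 2; 2 and 3 with library size alone) and 3 and 3 of 14 liver X receptor targets (3 and 3). They were 5 and 2 of 18 p53 targets (6 and 6; median -0.19, mean 0.13; 4 and 5 with library size alone), 4 and 2 of 24 macrophage identity genes (6 and 3; 2 and 3 with library size alone) and 2 and 2 of 25 autophagy genes (4 and 2; 2 and 4 with library size alone). For cholesterol the median was -0.05 and camera pointed up, and for liver X receptor targets camera pointed up and fry down. No marker of another cell type passed. Without DSF replicate 1, 399 genes were called in place of 1966, and with a fit of only these groups 524. Scaling by library size alone shifted the median of all genes by -0.10 and turned the split from 45.8% to 17.5% of calls upward, with 21 NF-kB genes up and none down. The excess of falls turned to an excess of rises with RLE scaling (1017 up and 906 down, 52.9% upward). It also did so with DESeq2 (1071 up and 916 down) and in the fit of only these groups (324 up and 200 down).

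**Figure D2:**
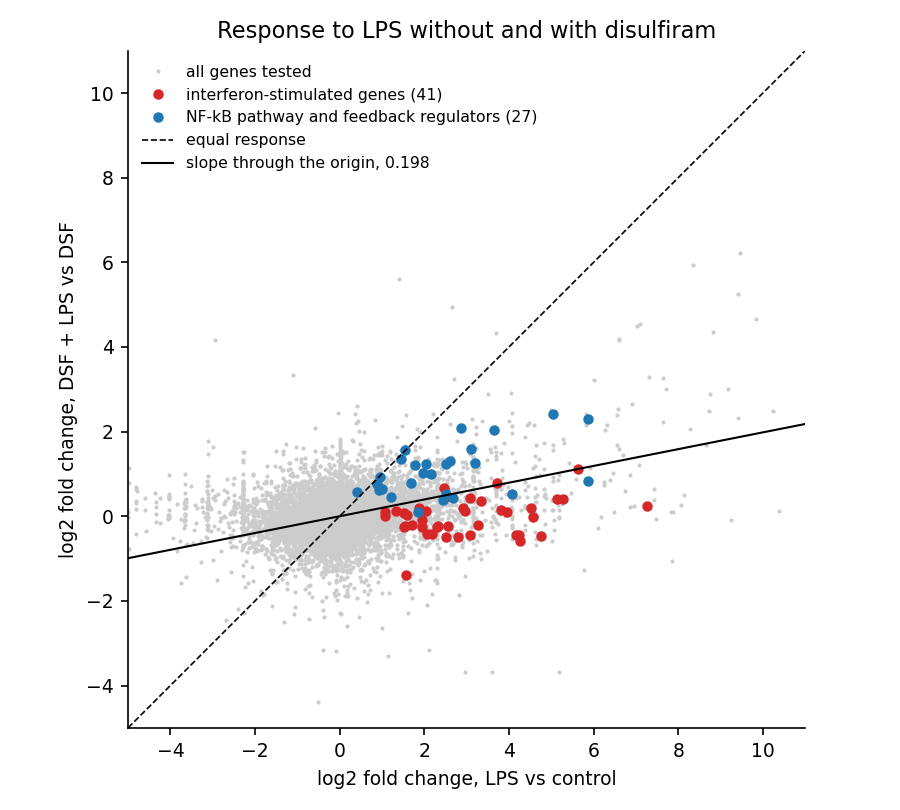
Log2 fold change of each tested gene with LPS, without DSF (horizontal axis, LPS with control) and with DSF (vertical axis, DSF+LPS with DSF); red points are 41 interferon-stimulated genes, blue points 27 NF-kB pathway genes, and 12 genes lie outside the axes. The dashed line marks equal responses and the solid line the fitted slope of 0.198; red points lie near 0 on the vertical axis and most blue points above it.

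The interaction tested whether the LPS response differed with DSF, gene by gene. It was smaller with the drug for most genes that LPS raised at least 2-fold, among them cytokines, chemokines and interferon-stimulated genes. For Tnf the 22.4-fold rise became 4.57-fold, for Cxcl10 the 79.2-fold rise became 4.47-fold, and for Ptgs2 the 93.3-fold rise became 3.21-fold. In all, 1981 genes had a lower and 1236 a higher LPS log2 fold change with DSF, 654 and 361 of them by at least 2-fold. Of the 872 genes that LPS raised at least 2-fold, 645 were called lower in the interaction, 0 higher and 227 neither way. Of the 594 that LPS lowered at least 2-fold, 407 were called higher, 0 lower and 187 neither way. DSF alone had raised 406 and lowered 178 of the 872 genes, and had raised 148 and lowered 246 of the 594. A level already raised by DSF also makes the LPS fold change smaller, so a lower interaction need not mean a lower final level. Ptgs2 and Cxcl2 were among the genes that DSF alone raised. The interaction counts of 0 are from edgeR, and at an unadjusted p under 0.05 and by DESeq2 they were 0 as well. The choice of both sets on the LPS response without DSF favours these interaction counts, since that response enters the interaction with the opposite sign. Of 105 genes that LPS raised at least 2-fold with DSF, 72 were called lower, 2 higher and 31 neither way. Of 39 that it lowered at least 2-fold with DSF, 13 were called lower, 2 higher and 24 neither way. The median log2 fold change of these 39 was -0.42 without and -1.265 with DSF.

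The interaction was -2.29 for Tnf on the log2 scale (SE 0.15, edgeR adjusted p = 6.45e-08), -4.86 for Ptgs2 (SE 0.12, adjusted p = 6.77e-12), -4.14 for Cxcl10 (SE 0.18, adjusted p = 9.32e-10), -4.89 for Ifit1 (SE 0.17, adjusted p = 2.18e-10) and -2.50 for Cd14 (SE 0.14, adjusted p = 1.34e-08). For Il1b it was -6.19 (adjusted p = 1.09e-05; -5.52, -7.87, -6.89 and -4.90 without control replicates 1 and 2 and DSF replicates 1 and 2). For Il6 it was -5.84 (adjusted p = 0.000227; -4.97 and -11.7 without control replicates 1 and 2), and for Nos2 -6.24 (adjusted p = 3.37e-05; -5.51 and -8.44 likewise). Ly96 (-0.23, SE 0.30, adjusted p = 0.657) and Tlr4 (0.19, SE 0.16, adjusted p = 0.469) did not pass.

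The largest negative values after Il12b (-10.28) and Csf2 (-7.75) were in Gbp5 (-7.02), Il1a (-6.97) and Serpina3f (-6.36). Il12b and Csf2 had 0 control counts and Serpina3f had 3, so these fitted values depend on the prior count. Il12b moved to -10.99, -8.97, -9.58 and -11.55 without DSF replicates 1 and 2 and DSF+LPS replicates 1 and 2, and Il1a to -6.11, -12.52 and -6.15 without control replicates 1 and 2 and DSF replicate 2. Csf2 was -8.46 without DSF replicate 1 and lost its call without DSF replicate 2 (-6.43, adjusted p = 0.0992). Serpina3f was -5.53, -9.99 and -7.08 without control replicates 1 and 2 and DSF replicate 1, and lost its call without DSF replicate 2 (-5.03, adjusted p = 0.183). The largest positive values were in Tmem44 (3.65), the anion transporter gene Slc26a11 (3.49), Adm, which encodes adrenomedullin (3.34), Cyp2s1 (3.16) and Lzts2 (3.13). Tmem44 lost its call without control replicate 2 (3.21, adjusted p = 0.0928) or LPS replicate 2 (2.69, adjusted p = 0.0904) and was 7.34 without LPS replicate 1.

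Of 41 interferon-stimulated genes 39 were lower in the interaction (41 adjusted over the list alone), all but Tgtp1 and Ifit1bl1, with Rsad2 at -4.73. So were 15 of 18 cytokines (17 adjusted over the list alone), with Il1rn at -3.17 and Osm at -2.70, 13 of 17 chemokines (14), with Ccl7 at -4.44, and 20 of 27 NF-kB genes (20), with Socs3 at -5.03 and Traf1 at -3.58. Of 19 effector genes 13 were lower and 1, Plau, higher (15 and 1), with Cybb at -2.30. Of 24 antigen presentation genes 10 were lower (11), with Cd40 at -2.67 and Tap1 at -1.82. Of 21 immediate early genes 10 were lower and 2, Ier5 and Klf4, higher (10 and 2), with Maff at -1.43. Higher were 7 of 25 autophagy genes with 3 lower (10 and 4), with Ulk1 at 1.41 and Lamp2, Optn and Atp6v1h lower. Also higher were 3 of 14 liver X receptor targets with Abca1 lower (5 and 1), namely Abcg1 at 1.27, Srebf1 and Lpl, and 4 of 29 oxidative phosphorylation genes with Cycs lower (4 and 1), namely Cox5b, Ndufb8, Ndufb10 and Sdhd. Lpl (0.34) lost its call without control replicate 1 or 2, DSF replicate 1 or LPS replicate 2 (adjusted p = 0.0700, 0.0556, 0.0546 and 0.0677), Cox5b (0.61) without control replicate 2, DSF replicate 1 or LPS replicate 1 (0.0755, 0.0623 and 0.0624), Ndufb8 (0.44) without LPS replicate 2 (0.0767) and Cycs (-0.67) without control replicate 2 (0.0547).

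Camera called these 10 lists, at adjusted p = 1.10e-43 for interferon, 1.19e-15 for cytokines, 9.24e-17 for chemokines, 4.49e-16 for NF-kB, 4.30e-11 for effector genes, 8.41e-06 for antigen presentation, 0.00829 for immediate early genes and oxidative phosphorylation, 0.00825 for liver X receptor targets and 0.0148 for autophagy. None held with an estimated correlation, at adjusted p = 0.0588 for cytokines and chemokines, 0.0626 for interferon and effector genes, 0.0659 for NF-kB, 0.144 for antigen presentation, 0.308 for liver X receptor targets, 0.345 for autophagy and 0.625 for immediate early genes and oxidative phosphorylation. The last was also lost without control replicate 1 (adjusted p = 0.0549).

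The lists that did not pass had, higher and lower, 1 and 6 of 24 TLR4 complex genes (1 and 6 adjusted over the list alone), with Irak2 at -1.60, 2 and 5 of 17 inflammasome genes (2 and 6), 5 and 7 of 27 NRF2 targets (6 and 8), with Slc7a11 at -3.28, 6 and 6 of 14 metal-handling genes (7 and 6; median 0.13, mean -0.02), 3 and 4 of 19 heat shock genes (3 and 4; median 0.01, mean -0.04; 4 and 2 with library size alone) and 1 and 5 of 28 unfolded protein genes (3 and 5; median -0.04, mean 0.04, median 0.009 with library size alone). They had 1 and 0 of 12 aldehyde dehydrogenases (1 and 0), 5 and 4 of 26 glycolysis genes (5 and 4), 2 and 6 of 22 cholesterol genes (2 and 6), 8 and 6 of 29 cell cycle genes (10 and 6), 5 and 4 of 18 p53 targets (7 and 4) and 8 and 7 of 24 macrophage identity genes (8 and 8; camera up, fry down). Of markers of other cell types, Batf3 (0.74) was higher and Camp (-4.38) and Kdr (-0.97) were lower. Batf3 and Camp each lost the call without any 1 library other than LPS replicate 2 and DSF+LPS replicate 2, at adjusted p up to 0.176 and 0.255, and Kdr without control replicate 2, DSF replicate 1 or 2, LPS replicate 2 or DSF+LPS replicate 2, at adjusted p up to 0.0954. Without LPS replicate 2 the interaction called 2003 genes in place of 3217, and without control replicate 1 2072.

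Across the 5709 genes called in either comparison, the slope of the LPS log2 fold changes with DSF on those without was 0.198 (95% interval over genes 0.174 to 0.223, which describes these libraries). It depended on the method and the genes: 0.798 by the inverse of the reverse regression, 0.428 over genes called in DSF+LPS with DSF and 0.279 over the inflammatory lists. In data simulated with equal responses in both states, the slope was 0.971 and the interaction called 0 of 1089 genes raised at least 2-fold. The simulation gave all groups the same spread, whereas replicates varied more with DSF+LPS than in control, as given below. It therefore does not cover calls that an unequal spread might add. Over the 872 raised genes the median log2 fold change was 2.01 without and 0.32 with DSF, and over the 594 lowered genes it was -1.44 and -0.23. The share of the LPS response kept with DSF is the LPS log2 fold change with DSF divided by that without. Its median was 0.470 for NF-kB genes, 0.272 for chemokines, 0.271 for effector genes, 0.195 for cytokines, 0.138 for antigen presentation genes and 0.001 for interferon-stimulated genes, each over members raised at least 2-fold. A share of 0.470 of a log2 fold change is a smaller share of the rise relative to the level before LPS. Genes that rose with LPS numbered 2485 without and 901 with DSF, of which 473 were shared (137 for independent lists), and genes that fell 2246 and 1065, of which 335 were shared (147).

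The log2 fold changes of LPS with control and of DSF+LPS with LPS, which share the LPS libraries, had a Pearson's r of -0.317 across 16304 genes, which are not independent replicates. Unchanged groups sharing those libraries gave -0.496 ± 0.0104 (SD over 100 simulations). The covariance was -0.342 against -0.0420 in the simulations, a difference of -0.300. The LPS libraries were not split, since each side would have kept only 1, so part of the excess may come from sharing them. Of the 872 genes raised by LPS, 553 were lower, 157 higher and 162 not called in DSF+LPS compared with LPS. Of the 594 lowered, 368 were higher, 59 lower and 167 not called.

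**Figure D3:**
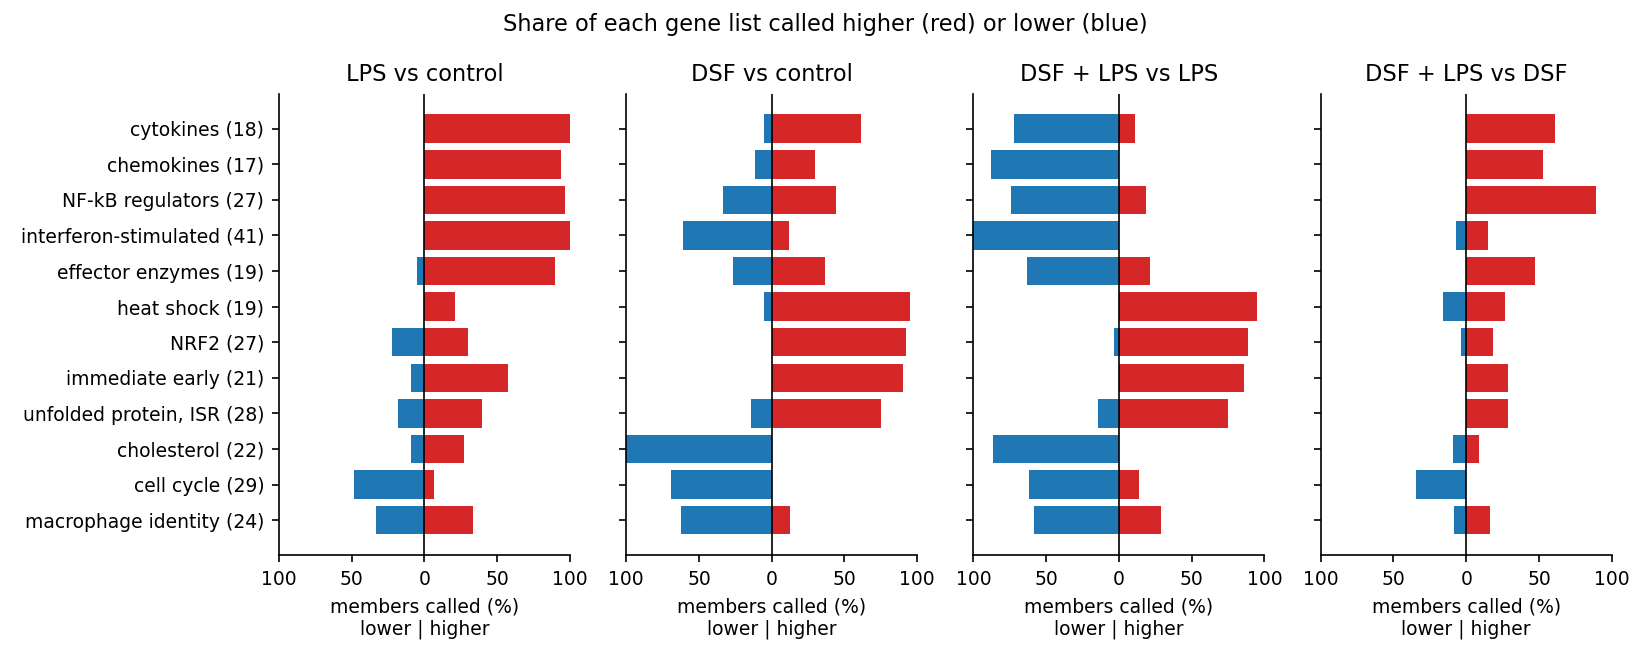
Percent of tested members of 12 gene lists called higher (red, right of 0) or lower (blue, left of 0) in 4 comparisons. LPS alone raised all 41 interferon-stimulated genes, DSF+LPS was lower than LPS in all 41, and with the drug present 24 of 27 NF-kB genes rose with LPS.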

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

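Of the tests in this part, those of same-strand neighbours, of other cell types and of reads from all other libraries were chosen only after the result was seen.

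Each result in this paragraph is here because the LPS response differed between cells with and without DSF by a test of the difference itself. The interaction called 3217 genes. Among genes named in advance, the difference of the LPS log2 fold changes was -4.86 for Ptgs2, -6.19 for Il1b, -5.84 for Il6, -4.14 for Cxcl10, -6.24 for Nos2, -2.29 for Tnf, -2.50 for Cd14 and -4.89 for Ifit1. The largest falls were in Il12b (-10.3), Csf2 (-7.75), Gbp5 (-7.02), Il1a (-6.97) and Serpina3f (-6.36), and the largest rises in Tmem44 (3.65), Slc26a11 (3.49), Adm (3.34), Cyp2s1 (3.16) and Lzts2 (3.13). The values of Il12b, Csf2 and Serpina3f rest on 0 to 3 control counts and depend on the prior count. Members called lower numbered 15 for cytokines, 13 for chemokines, 20 for NF-kB, 39 for interferon, 10 for immediate early genes, 13 for effector genes and 10 for antigen presentation, and members called higher numbered 3 for liver X receptor targets, 4 for oxidative phosphorylation and 7 for autophagy. Members called the other way numbered 2 for immediate early genes, 1 for effector genes, 1 for liver X receptor targets, 1 for oxidative phosphorylation and 3 for autophagy. None of these lists passed with an estimated correlation, at adjusted p from 0.0588 (cytokines and chemokines) to 0.625 (immediate early genes and oxidative phosphorylation). Without control replicate 2 the values were -7.87 for Il1b, -11.7 for Il6, -8.44 for Nos2, -12.52 for Il1a and -9.99 for Serpina3f, and without DSF replicate 2 -4.90 for Il1b, -6.15 for Il1a and -8.97 for Il12b. Csf2 (-6.43, adjusted p = 0.0992) and Serpina3f (-5.03, adjusted p = 0.183) were not called without DSF replicate 2, nor Tmem44 without control replicate 2 (3.21, adjusted p = 0.0928) or LPS replicate 2 (2.69, adjusted p = 0.0904). The count was 2003 without LPS replicate 2 and 2072 without control replicate 1, and further values are in the report.

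The first pattern weighed is that genes near 0 counts without DSF gained counts with it. Of 16070 genes with at most 3 counts over the 4 libraries without the drug, 252 had at least 10 counts in each of the 4 libraries with it, 203 of them protein-coding, among them Cacna1h, Uncx, Mmp28, Plekha6 and Usp17le. In the other direction, of 12954 genes silent with the drug, 0 had at least 10 counts in each library without it. Such a loss would also need RNA made before the drug to be gone by sampling, so the 2 directions are not like for like. Genomic DNA is argued against as the only source, since it would give counts by exonic length. The share of silent genes with no count exceeded that expectation by at least 32.3 percentage points in the 4 libraries with DSF. The expectation was set by the total over all silent genes, of which the top 1% held 35.5% to 39.0% in those libraries. A smaller part from DNA was therefore not tested. RNA from cells of another type stays open. Over 5 lists of markers the highest sum in those libraries was 18.1 CPM, for dendritic cells, against 15.9 and 17.0 CPM in control, but no table measures the marker level that cells supplying the gained genes would bring. The other 4 sums were higher with DSF alone than in control, among them fibroblast markers (4.42 and 3.25 against 1.12 and 1.65 CPM), neutrophil markers (1.66 and 1.96 against 0.449 and 0.803) and lymphocyte markers (7.05 and 7.43 against 4.49 and 4.86). Cells of a type not listed were not tested, and no sort is named that would have removed them.

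Transcription running on past the end of an expressed neighbour stays open as an explanation for part of these genes. It may put counts into a downstream gene, and the test planned for it asked whether gained genes lay past the 3' end of an expressed gene within 20 kb more often than before its 5' end, relative to silent genes that did not gain. The ratio of the odds ratios was 1.59 (1.05 to 2.48), under the 2 set as its bound, and from 1.18 to 1.62 over 6 choices of window and neighbours, so it could not decide, and 4 of the 6 intervals included 1. Over neighbours on the same strand the ratio was 2.61 (1.64 to 4.47): 49 of 234 gained genes with no overlapping expressed gene (20.9%) lay past such a 3' end, against 4.31% of those not gained, and 9.83% against 4.66% lay before a 5' end. Gained genes also lay more often near expressed genes on the other strand, with odds ratios of 2.61 where 3' ends faced each other and 2.85 where 5' ends did, against 5.92 and 2.27 on the same strand. At this distance most gained genes lay in neither position, and what raised them stays open. A direct effect of the drug on these genes is the biological alternative, and it was not tested. Gene order came from an older assembly than the one the submitters name.

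The second pattern is that interferon-stimulated genes kept less of their LPS response with DSF than NF-kB genes did. The median kept share of the log2 fold change was 0.00136 for 41 interferon genes, of which 40 kept under 0.25, and 0.470 for 22 NF-kB genes. A difference in the size of the LPS response or in abundance is argued against for the low share of the interferon genes. Here 10000 random lists of other LPS-raised genes, matched to the interferon list on both, had medians from 0.149 to 0.293 (the middle 95%). The prediction had named the NF-kB list for the matching. The NF-kB share of 0.470 lay above that range, and no lists were matched to it. A shift of all genes by the scaling could hardly make the gap, since it moves both lists alike. Their median LPS log2 fold changes were also close (2.57 for interferon and 2.51 for NF-kB genes). The gap was 0.468 with scaling factors and 0.515 with library size alone, a test that could hardly have come out otherwise. Separate effects of the drug on the 2 branches below TLR4 may explain the gap, as a hypothesis found in these data and not itself tested. The share kept by NF-kB genes may also include genes that DSF alone moved, and receptor activity was not measured.

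The last pattern is low counts of LPS-induced genes in control replicate 2, such as 15 counts of Il6 and 37 of Il1b against 0 and 6 in control replicate 1. Reads carried over from other libraries may explain it. The planned test compared the share of the source level in genes raised by DSF with that in genes raised by LPS, both chosen at 1 count or fewer in control replicate 1, and gave a ratio of 1.03 (0.661 to 1.5). This says nothing, because choosing on 1 control library makes the other look higher. With the choice made on control replicate 2, DSF-raised genes stood at 0.799% of the source level in replicate 1, against 0.864% in the planned direction, and LPS-raised genes at 0.424% (0 to 0.595, 3 genes) against 0.837% (0.546 to 1.95, 12 genes). A later test chose genes without the control libraries. The excess of control replicate 2 was 0.045% of the source level (-0.0895 to 0.060) for 38 DSF-raised genes and 0.206% (0.0102 to 0.453) for 15 LPS-raised genes, whose counts summed to 710 and 1033. The first fell short of the share of the second set for carry-over in 84.8% of resamplings, too few to decide, so carry-over, a slight activation of that culture and chance cannot be told apart with these counts.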

How the results depend on the processing

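Of the alternatives in this part, limma-voom with sample weights, the filter of a mean CPM of at least 1 without DSF, and those of the correlation were chosen only after the data were seen. Where 1 library is left out, the lone library of its group is assumed to vary like the other groups. The groups did not vary alike, with a chi-square between replicates per degree of freedom from 3.88 in control to 13.33 with DSF+LPS.

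The counts of called genes of all 5 comparisons, LPS with control, DSF with control, DSF+LPS with LPS, DSF+LPS with DSF and interaction in this order, stayed within 1.5 times of those reported under RLE scaling, library size alone, no filter, both stricter filters, DESeq2 and limma-voom. With a threshold of 0.5 on the log2 fold change they were 1647, 4740, 6180, 104 and 952, a stricter question by construction. For DSF+LPS with DSF, limma-voom with sample weights gave 1075 and a fit of only those 2 groups 524, while such a fit gave 6043, 9657 and 9890 for the comparisons before it. The sample weights were 0.599 and 0.591 for DSF+LPS, 0.918 and 0.92 for DSF, and from 1.34 to 1.36 for control and LPS. The 1 shared spread may thus be too small for DSF+LPS with DSF and too large for LPS with control. Leaving out 1 library gave 3146 to 5545, 7834 to 10423, 9221 to 10845, 399 to 2406 and 2003 to 3797; the values 3146, 399 and 2003 came without control replicate 2, DSF replicate 1 and LPS replicate 2. The cause was not tested.

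With the sample number as a replicate block the counts were 4734, 9421, 10596, 2129 and 3226, and all 52 list calls and every named gene call but 1 stayed (Camp in the interaction, -4.21, adjusted p = 0.0570). Residuals of samples with the same number correlated across groups with r from -0.119 to 0.0531, so the numbers gave no sign of pairing.

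The slope of 0.198 was 0.798 by the inverse of the reverse regression, which puts all scatter on the other axis, 0.428 over genes called in DSF+LPS with DSF only, a set chosen on the drug-treated response, and 0.279 over the inflammatory lists. It ran from 0.172 to 0.240 without 1 library. The correlation of LPS with control and DSF+LPS with LPS, -0.317, was -0.291 with library size alone and from -0.348 to -0.301 without 1 library; the cause was not tested.

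Lists passing numbered 8, 11, 14, 9 and 10 in the order above. With an estimated correlation they numbered 6, 0, 0, 2 and 0, and 44 of 52 calls were lost; the cause was not tested. With fry, which asks another question, they numbered 16, 21, 22, 8 and 11, and 5 of 52 calls were lost (in DSF+LPS with DSF, immediate early genes at 0.117 and unfolded protein and oxidative phosphorylation genes at 0.056; in the interaction, immediate early genes at 0.195 and oxidative phosphorylation at 0.18). Without 1 library they numbered 8 to 10, 11 to 12, 14 to 15, 9 to 11 and 9 to 11, and 3 of 416 calls were lost.

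Some directions turned, all in genes that were not called. Ly96 in LPS with control (0.13) was -0.0303 with library size alone and ran from -0.0625 to 0.285 without 1 library. Tlr4 in DSF+LPS with LPS (-0.11) was 0.002436 with the mean CPM filter and ran from -0.264 to 0.0402 without 1 library. Ly96 in DSF+LPS with DSF ran from -0.218 to 0.0172. In DSF with control Il1b ran from -0.699 to 2.26, Il6 from -0.515 to 6.22 and Nos2 from -0.182 to 2.75, the highest without control replicate 2 each time. The cause was not tested.

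Near the threshold, Ifit1 in DSF with control (-0.22) was called with library size alone (-0.33, adjusted p = 0.0435), and in DSF+LPS with DSF (0.40) with the strict and the mean CPM filters (adjusted p = 0.0489 and 0.0423). In DSF+LPS with DSF, Il6 was not called by DESeq2 (2.91, adjusted p = 0.0711), nor Cd14 in a fit of only those 2 groups (0.46, adjusted p = 0.0629). Tlr4 in DSF with control was not called with the strict filter (-0.26, adjusted p = 0.0516), DESeq2 (-0.29, adjusted p = 0.0612) or the mean CPM filter (-0.22, adjusted p = 0.104). The cause was not tested.

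Over all 420 values of named genes, DESeq2 kept direction and call for 410 of 419, library size alone for 413, the fold threshold for 324, the strict filter for 396 of 398 and a fit of only 2 groups for 313 of 332; of 3360 values without 1 library 3214 kept both. Low counts limited Il1b, Il6 and Nos2 without LPS, where 0 to 37 counts per control library set the fold changes, and a fit of only the groups compared cannot be made for the interaction.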

Other observations

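The gene groups of the first paragraph, histone and Usp17 or Tex19 genes, were chosen only after the values were seen; the proteasome test of the last was written before its result.

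Of 56 tested histone genes of the chromosomal clusters, whose messages normally end without a poly(A) tail, 55 rose in DSF with control, with a median log2 fold change of 4.13 and a sum of 91.4 CPM in control and 681 CPM with DSF. Much of both sums came from Hist1h4i (25.4 and 211 CPM) and Hist1h2bc (18.4 and 155 CPM). In DSF+LPS with LPS all 56 rose, from 72.2 to 775 CPM. Examples are Hist1h2ac (0.247 to 10.0 CPM) and Hist1h1c (25.6 to 53.1 CPM) with DSF alone. The group passed camera (adjusted p = 5.00e-14) and did not with an estimated correlation (adjusted p = 0.181). Of 12 replication-independent histone genes 3 rose and 2 fell with DSF. All 7 tested Usp17 and Tex19 genes rose with DSF, from 0.338 to 182 CPM in sum, most of it from Tex19.1 (130 and 179 CPM in the DSF libraries), while the other 6 reached 2.39 to 7.99 CPM each (camera adjusted p = 0.00375, and 0.533 with an estimated correlation). Genes near 0 CPM without DSF could pass the filter on low counts only through the libraries with it. Examples are Usp17lc, at 0 CPM in control and LPS, and Hist1h4c, at 0.0259 and 0.0246 CPM. The filter therefore favoured the shares that rose and the camera results of these groups. How reads were split among near-identical copies in these groups is uncertain.

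Summed macrophage identity genes stood at 6149 and 6144 CPM in the control libraries, 4599 and 4710 with DSF, 5447 and 5371 with LPS and 4579 and 4756 with both.

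A block of the proteasome was a candidate explanation for the rise of heat shock genes with DSF, as cells then raise genes of its subunits. The test gave a median log2 fold change of -0.00546 over 34 subunit genes in DSF with control (quartiles -0.103 and 0.110), with 5 called higher, 6 lower and 23 neither way, under the 0.1 set in advance as the bound against it. These values argue against a block that had raised subunit RNA by the time of sampling. A block without such a rise is not covered, and proteasome activity was not measured.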
